A study of Mus musculus with 16 samples.

How the data were processed

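The series holds bulk RNA-seq of neutrophils sorted from livers of 8 mixed bone marrow chimeras. Per the labels, irradiated (about 1000 cGy) wild-type hosts received 50% CD45.1 wild-type and 50% CD45.2 Ifngr1-deficient marrow, reconstituted for 8 weeks, were given MC38 flank tumours and were treated with a CD40 agonist 1 week later. Liver neutrophils were sorted by CD45 type 2 days after treatment, and libraries were made from 1 ng of RNA by oligo-dT priming with the SMART-Seq chemistry, 13 cycles of PCR and a Nextera XT preparation. Such libraries carry no molecular identifiers and do not mark strand, so reads of overlapping antisense genes cannot be told apart and counts include PCR copies. Groups (WT and Ifngr1_KO) and mouse numbers came from the sample titles, and the series design text states that the samples with 1 number came from 1 mouse.

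The deposited table holds whole-number estimated counts per Ensembl gene for 16 samples, 1 column each, with no scaling between samples. Per the submitters' processing notes, Salmon 0.14.2, DESeq2 1.22.1 and genome build mm10 were used. What DESeq2 was used for, the transcript annotation and any filters are not given in the sources used here. Because Salmon gives fractional estimates, the whole numbers were read as estimated counts rounded before deposit. The table lists 54532 gene identifiers, of which 25008 had a count in any sample. Names and 1-based positions were taken from the GENCODE annotation of the same build, and 37 identifiers had no name in it, holding at most 9.4e-04% of any library.

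Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr with the group labels, which kept 9851 genes holding 99.7% of all counts, and libraries were scaled by TMM. Each gene was tested by the quasi-likelihood F-test (glmQLFit and glmQLFTest, robust) with mouse as a block and genotype as the tested term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are Ifngr1_KO over WT on the log2 scale. Their SE is the size of the log2 fold change divided by the square root of F. CPM values are TMM-scaled, given as mean ± SD over 8 mice. Totals of 12.5 to 21.7 M counts per library set the precision, so genes at or below a few CPM rest on few counts per library.

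Before the data were examined, 33 gene lists, the rule for the genes named, the tests, the 20 Mb windows and most alternatives were fixed. The lists hold 602 entries for 555 genes, of which 467 were tested. They cover interferon responses, antigen presentation, neutrophil functions, RNA quality and markers of other liver and blood cells. List direction was tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 33 lists, beside camera with an estimated correlation and fry. Camera compares a list with the other genes, and fry asks whether the genes of a list move on balance in 1 direction. Named genes were Ifngr1; among called genes with a mean log2 CPM of at least 3 and the same direction in at least 7 of 8 mice, the 12 with the largest rise and the 12 with the largest fall, skipping predicted genes and antigen receptor segments; for each list up to 4 called members with the smallest p, or up to 2 with the highest CPM where none was called; and up to 5 called genes per window. The rule was met by 37 higher and 194 lower genes before the limit of 12, and it named 103 distinct genes, of which some are not reported here.

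Library measures were compared within mice by exact two-sided sign-flip tests over the 8 pairs, adjusted over 6 measures. Calls near Ifngr1 and Ptprc were compared with the rest of the genome by Fisher's exact test. The pairing was checked by correlating, across genes, the deviations of the 2 libraries of a mouse from their group means. The mean correlation was 0.138 within mice (range 0.0246 to 0.314) and -0.0180 between mice, and 4 of 8 WT libraries correlated best with the Ifngr1_KO library of their own mouse. The block was kept because the mouse is the shared source of both libraries.

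Alternatives were no mouse block, DESeq2 size factors or library totals in place of TMM, and other low-count filters. DESeq2 1.42.0 and limma-voom with quality weights per library were used in place of edgeR. Further alternatives left out each mouse or used other thresholds, other windows and other set tests. Transcript length offsets and the mitochondrial share as a covariate were added after seeing the data. The test was tried on counts simulated from the real means, library sizes and dispersions for 9851 genes in the same paired comparison, with 200 genes changed. It called 2% of 50 genes changed by 1.5-fold, 22% of 50 at 2-fold, 58% of 50 at 4-fold and 82% of 50 at 8-fold, each in the right direction, with 1 call among unchanged genes. No sample was left out of the comparison.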

Results

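RNA was sequenced from neutrophils sorted out of the livers of 8 mixed bone marrow chimeras, numbered 2 to 9. A mixed chimera is an irradiated mouse whose blood system is rebuilt from the marrow of more than 1 donor, so that cells of both genotypes live in the same animal. Each mouse carried wild-type marrow marked by CD45.1 and Ifngr1-deficient marrow marked by CD45.2, in equal parts. CD45.1 and CD45.2 are allelic forms of the surface protein encoded by Ptprc, and the sort used them to separate the genotypes. The mice also carried flank tumours of the colon carcinoma line MC38 and had received an agonist antibody against CD40, a costimulatory receptor whose engagement can inflame the liver. Livers were taken 2 days after the antibody. Each mouse gave 1 WT and 1 Ifngr1_KO library, which makes 8 libraries per group and 16 in all. The comparison asks which transcripts of liver neutrophils depend on their own receptor for interferon gamma (IFN-gamma) when both genotypes share the same liver, tumour and treatment. Marrow donor, CD45 type and sort gate went with genotype in every mouse. Their effects cannot be told apart from that of the receptor, for any gene or library measure.

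The 16 libraries held 12.5 to 21.7 M estimated counts each. WT libraries held 16.9 ± 3.27 M and Ifngr1_KO libraries 13.9 ± 1.502 M (SD, n = 8), and the Ifngr1_KO total was above the WT total in 1 of 8 mice (exact two-sided sign-flip test, p = 0.0156, adjusted p = 0.0469 over 6 library measures). Counts of at least 10 were found for 10072 ± 395 genes in WT and 10155 ± 463 in Ifngr1_KO (SD, n = 8). No columns were identical, and correlations between libraries on the log2 scale ran from 0.728 to 0.928. Mitochondrially encoded mRNAs took 0.595 ± 0.272% of WT counts and 1.39 ± 0.656% of Ifngr1_KO counts (SD, n = 8), higher in Ifngr1_KO in 6 of 8 mice (exact sign-flip p = 0.0313, adjusted p = 0.0625). The Ifngr1_KO library of mouse 7 stood apart from the others. Its median correlation with the rest was 0.762, its 10 most abundant genes took 22.8% of its counts, and its mitochondrial share was 2.503%.

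**Figure D1:**
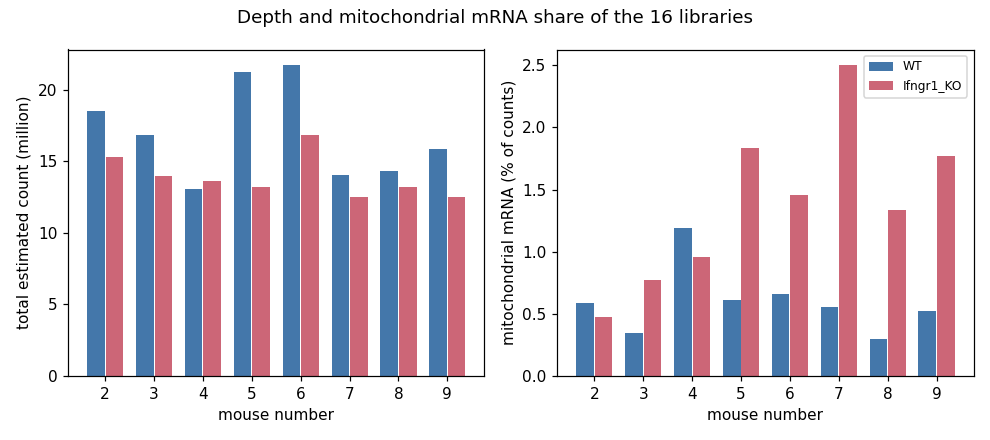
Total estimated count in M counts (left) and mitochondrial mRNA as percent of counts (right) for each mouse, with 1 bar per library, WT in blue and Ifngr1_KO in red. The Ifngr1_KO total exceeded the WT total in 1 of 8 mice, and the mitochondrial share was higher in Ifngr1_KO in 6 of 8 mice, reaching 2.503% in mouse 7.

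Ifngr1, the ligand-binding chain of the IFN-gamma receptor (ENSMUSG00000020009, chromosome 10, 19591949 to 19610229 in mm10), was lower in the Ifngr1_KO library of all 8 mice. Its level was 305 ± 46.6 CPM in WT and 83.9 ± 29.5 CPM in Ifngr1_KO (SD, n = 8). The log2 fold change was -1.94 (SE 0.20, adjusted p = 2.5e-04), so that Ifngr1_KO kept 26.1% of the WT level. By mouse, the WT levels of Ifngr1 from mouse 2 to mouse 9 were 310.5, 307, 256, 358, 353, 287, 228 and 343 CPM. The Ifngr1_KO levels in the same order were 53.8, 119, 91.5, 63.4, 104, 38.8, 84.2 and 116 CPM. The highest Ifngr1_KO library therefore lay below the lowest WT library. These values are totals over the gene, without resolution along the transcript, so they check the labels and do not measure receptor protein.

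Loss of the receptor went with a large fall of interferon-induced transcripts and a smaller set of increases. Of 9851 genes tested, 229 were lower and 47 were higher in Ifngr1_KO at an adjusted p under 0.05. The fall reached at least 2-fold for 138 genes and at least 4-fold for 62, against 29 and 4 among the genes that rose. Among genes with a mean log2 CPM of at least 3, the deepest falls were in Tgtp1, a T cell specific GTPase of the immunity-related GTPase family, from 1050 ± 365 to 9.38 ± 8.43 CPM (log2 fold change -7.32, SE 0.61), and in Batf2, an interferon-induced transcription factor, from 173 ± 68.9 to 1.63 ± 1.08 CPM (-6.85, SE 0.45; SD, n = 8). Each of the 276 genes went in its direction in at least 7 of 8 mice.

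The other 10 of the 12 largest falls among genes with a mean log2 CPM of at least 3 were spread over several families. Clic5, a chloride intracellular channel protein, fell by 6.61 on the log2 scale (SE 0.90), and Tgtp2, a close copy of Tgtp1, fell by 5.17 (SE 0.16, adjusted p = 4.0e-08). Ctse, which encodes the aspartic protease cathepsin E, fell from 337 ± 36.1 to 12.1 ± 2.87 CPM. The guanylate-binding proteins Gbp4, Gbp6 and Gbp8, large GTPases that attack the vacuoles of intracellular microbes, had log2 fold changes of -4.62, -4.44 and -4.23. Gbp8 was not called without mouse 2, 8 or 9 (adjusted p = 0.0540, 0.0664 and 0.0551) or with the mitochondrial covariate (-3.44, 0.607), and Clic5 was not with the covariate (-4.66, 0.0737). Calhm6, a member of the calcium homeostasis modulator family, had -4.03, and the interferon-induced transcript AW112010 had -3.56, from 264 ± 61.7 to 23.5 ± 8.84 CPM. H2-M3, a nonclassical class I molecule that presents formylated peptides, had -3.53, and the phospholipase gene Pla2g16 had -3.48. All of these were lower in Ifngr1_KO in 8 of 8 mice. Tgtp1 and Tgtp2 are near-identical copies, and the annotated spans of Gbp4 and Gbp8 overlap, so the split of reads within each pair is uncertain.

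The 12 largest increases at the same minimum level were smaller, and all were higher in Ifngr1_KO in 8 of 8 mice. Hic1, a transcriptional repressor, rose from 4.55 ± 2.87 to 25.9 ± 18.9 CPM (log2 fold change 2.41, SE 0.28, adjusted p = 6.3e-04). Gdf15, a stress-induced cytokine of the TGF-beta family, rose from 18.7 ± 15.0 to 71.2 ± 56.3 CPM (1.94, SE 0.32). Mmd had a log2 fold change of 1.75, Igfbp6, a binding protein for insulin-like growth factors, 1.70, and the small nuclear RNA Rn7sk 1.64. Cenpb, which binds centromeric DNA, had 1.54 and Cdc34, a ubiquitin-conjugating enzyme, 1.46. The nucleotide receptor P2ry6 rose from 14.4 ± 2.80 to 41.0 ± 8.26 CPM (1.504, SE 0.18), and Klf10, a TGF-beta induced zinc finger factor, from 50.8 ± 13.4 to 140 ± 76.2 CPM (1.32, SE 0.24). Rbm6 had 1.30. Gpr35, a G protein-coupled receptor, rose from 44.6 ± 17.4 to 99.9 ± 19.99 CPM, and Gstm1, a glutathione transferase, from 88.0 ± 15.2 to 200.1 ± 60.6 CPM. Without the mouse block, Gdf15, Mmd, Igfbp6, Cenpb and Cdc34 were no longer called, at adjusted p of 0.162, 0.100, 0.100, 0.0976 and 0.0501. With the mitochondrial share as a covariate 11 of the 12, all but P2ry6, were no longer called, at adjusted p of 0.0639 to 0.946. Their log2 fold changes were then 2.48 for Gdf15, 1.95 for Hic1, 1.65 for Mmd, 1.60 for Igfbp6, 1.43 for Gpr35, 1.40 for Cdc34, 1.13 for Cenpb, 0.92 for Gstm1, 0.87 for Rbm6, 0.60 for Klf10 and 0.49 for Rn7sk. The mitochondrial share differed between genotypes (means of 0.595% in WT and 1.39% in Ifngr1_KO), so this covariate overlaps with the tested term and can cost power. Ifngr1 itself went to an edgeR adjusted p of 0.0428 with it, at a log2 fold change of -1.89. Rbm6 was also not called with no filter (adjusted p = 0.0670) or without any 1 of the mice other than mouse 4 (0.0591 to 0.117), with log2 fold changes of 1.15 to 1.42. Cenpb was not called with no filter (0.0618) or without mouse 3, 4, 6, 8 or 9 (0.0653 to 0.0883), Rn7sk without mouse 3, 5, 6, 8 or 9 (0.0783 to 0.124), Mmd without mouse 3 (0.0557) and Cdc34 without mouse 6 (0.0507).

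The genes were tested with edgeR's quasi-likelihood F-test with mouse as a block, and 1602 genes had an unadjusted p under 0.05. With library totals in place of trimmed-mean scaling the split was 164 lower and 102 higher, and the median log2 fold change of all genes moved from 0.046 to 0.16. Without mouse 7 the counts were 334 lower and 78 higher, and 264 of the 276 calls were shared. Without mouse 3 they were 144 and 19, with 159 shared. DESeq2 gave 572 lower and 488 higher, and the mitochondrial share as a covariate 65 and 4. Without the mouse block 216 genes were lower and 52 higher, 215 of the 276 calls were shared, and 18 of the genes named here were not called.

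Several calls of named genes were lost under 1 alternative or without 1 mouse. A lost call need not mean a lost change. With the mitochondrial covariate Gsdmd had a log2 fold change of -0.75 (main fit -0.78), but Tlr2 had -0.32 (-0.73). Leaving out a mouse also removes a pair, so calls near the threshold can be lost whichever mouse is left out. With the mitochondrial share as a covariate, beside the 11 increases, Clic5, Gbp8, Herc6, Xaf1, Stat2, Il15, Ier3, Nfkbie, Nfkbib, Gsdmd, Clec7a, Tlr2, Lyz2, Ngp, Ltf, Cybb, Hdc, Fpr1, Cxcr4, Icam1, Ptafr, Bid, Nos2, Sod2, Cfb, Havcr2, Icosl, Adgre1, Ly6c2, Vnn3 and Mybph were not called. Library totals ended the calls of Xaf1, Nfkbie, Clec7a, Tlr2, Ltf, Cybb, Fpr1, Icam1, Ptafr, Bid, Icosl and Vnn3, and no filter those of Cenpb, Rbm6, Fpr1, Ptafr, Bid, Havcr2 and Icosl. DESeq2 size factors ended those of Ptafr and Icosl, a mean CPM of at least 10 those of Xaf1 and Fpr1, length offsets that of Xaf1 and a minimum of 10 counts in 8 samples that of Icosl. With 1 mouse left out, calls were lost at least once for Mmd, Rn7sk, Cenpb, Cdc34, Rbm6, Gbp8, Herc6, Xaf1, Nfkbie, Nfkbib, Clec7a, Tlr2, Ltf, Cybb, Fpr1, Icam1, Ptafr, Bid, Sod2, Havcr2, Icosl and Vnn3, and of these only Rbm6 lost its call without mouse 7.

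**Figure D2:**
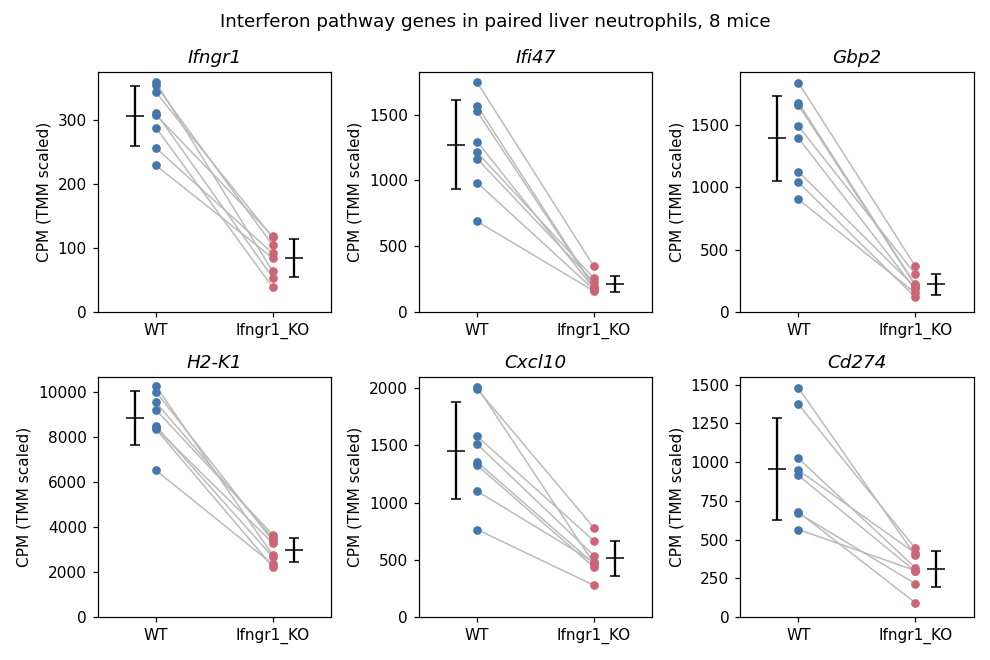
Level in CPM of Ifngr1, Ifi47, Gbp2, H2-K1, Cxcl10 and Cd274 in WT (blue) and Ifngr1_KO (red) neutrophils, with a grey line joining the 2 libraries of each mouse and black bars giving the mean ± SD (n = 8). All 6 genes were lower in the Ifngr1_KO library of all 8 mice.

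Genes induced by IFN-gamma fell nearly as a block. Of 24 tested members of the IFN-gamma list, 18 fell and none rose, with 6 not called (19 fell when adjusted over the list alone). The median log2 fold change was -2.10 (camera adjusted p = 3.2e-90; adjusted p = 4.4e-04 with an estimated correlation). Gbp2 fell from 1391 ± 337 to 221 ± 81.1 CPM (SD, n = 8). Ifi47, an immunity-related GTPase, had a log2 fold change of -2.56 (SE 0.14) and the immunoproteasome subunit Psmb9 -1.85 (SE 0.12). The list of guanylate-binding proteins and immunity-related GTPases had 14 of 15 tested members lower (15 adjusted over the list alone) and a median of -2.70 (camera adjusted p = 7.8e-105; adjusted p = 4.6e-04 with an estimated correlation). The summed level of this list was 7287 ± 1921 CPM in WT and 1101 ± 349 CPM in Ifngr1_KO.

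Transcripts for antigen presentation through MHC class I fell with it. In the class I list 14 of 18 members fell, none rose and 4 were not called (15 lower adjusted over the list alone), with a median log2 fold change of -1.74 (camera adjusted p = 2.0e-62; adjusted p = 0.00207 with an estimated correlation). The classical heavy chain gene H2-K1 fell from 8833 ± 1190 to 2985 ± 546 CPM (-1.57, SE 0.10). The peptide editor Tapbpl had -2.32 (SE 0.12), H2-Q7 -2.14 (SE 0.11) and H2-T22 -1.90 (SE 0.11). The H2-Q and H2-T genes are close relatives, and reads could be split among them in more than 1 way. All 5 members of the immunoproteasome list fell, also when adjusted over the list alone (median -1.74, camera adjusted p = 3.1e-29; adjusted p = 0.00765 with an estimated correlation). Among these, Psmb8 went from 1320 ± 260 to 443 ± 91.2 CPM, Psme2 from 813 ± 170 to 243 ± 48.7 CPM and Psmb10 from 300 ± 74.6 to 85.5 ± 25.8 CPM (SD, n = 8).

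Genes usually assigned to type I interferon moved far less. Of 27 tested members 2 fell, none rose and 25 were not called (8 lower adjusted over the list alone), with a median log2 fold change of -0.24 (camera adjusted p = 3.3e-04; adjusted p = 0.185 with an estimated correlation). The 2 that fell were Herc6, a ubiquitin ligase for ISG15, with -0.89 (SE 0.16), and Xaf1, a proapoptotic factor, with -0.60 (SE 0.14), and neither call was stable. Xaf1 was not called without the mouse block (edgeR adjusted p = 0.103), at a log2 fold change of -0.58. It was also not called without any 1 of the mice other than mouse 7 (0.0751 to 0.128), at -0.64 to -0.53. Herc6 was not called without mouse 8 or 9 (0.0583 and 0.0504, at -0.82 and -0.83) or with the mitochondrial covariate (-0.74, 0.553). Averaged within mice, the guanylate-binding and immunity-related GTPase list changed by -3.22 ± 0.56 on the log2 scale and the type I list by -0.27 ± 0.30 (SD, n = 8). The difference of -2.95 ± 0.34 had the same sign in 8 of 8 mice (exact two-sided sign-flip test, p = 0.00781, the smallest p that 8 pairs allow).

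MHC class II genes and the receptor pathway itself had few called members. In the class II list 1 of 8 members fell, Ctss, which encodes cathepsin S, from 610 ± 89.6 to 287 ± 30.5 CPM (5 lower adjusted over the list alone). The list median was -0.42 (camera adjusted p = 3.3e-04; adjusted p = 0.0718 with an estimated correlation). In the list of interferon receptors, JAKs, STATs and their inhibitors 3 of 22 fell and none rose (6 lower adjusted over the list alone), among them Ifngr1 and Stat2, the latter from 227 ± 52.4 to 106 ± 39.8 CPM (SD, n = 8), a log2 fold change of -1.18, or -0.73 with the mitochondrial covariate (edgeR adjusted p = 0.525). That list had a median of -0.43 (camera adjusted p = 2.4e-05; adjusted p = 0.195 with an estimated correlation), and of -0.10 with the mitochondrial covariate (adjusted p = 0.114).

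**Figure D3:**
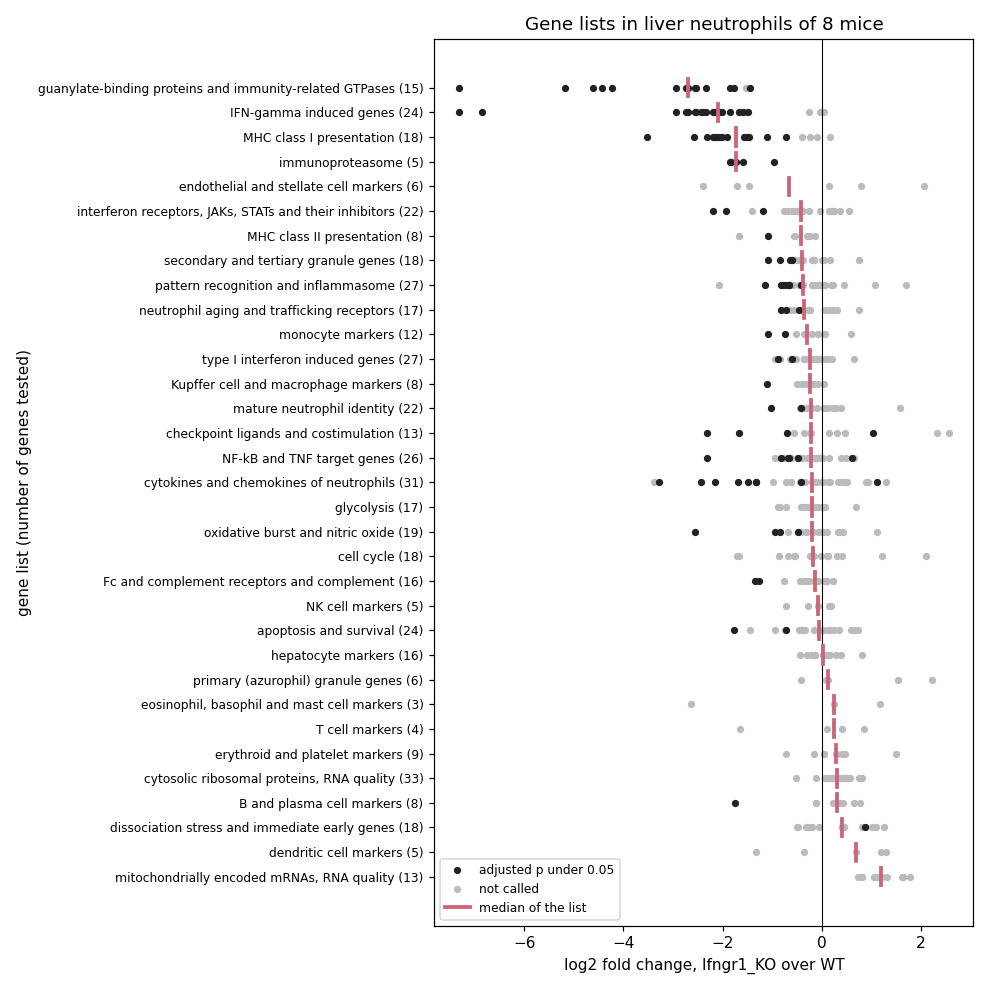
Log2 fold change of Ifngr1_KO over WT for the tested members of the 33 gene lists, with 1 point per gene, black where called at an adjusted p under 0.05 and grey where not, and a red bar at the median of each list. The lowest medians, -2.70, -2.10, -1.74 and -1.74, belong to the guanylate-binding and immunity-related GTPases, the IFN-gamma list, MHC class I and the immunoproteasome.

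Most cytokine and chemokine genes were not called. Of 31 tested cytokine and chemokine genes 8 fell, 1 rose and 22 were not called (10 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 3.0e-05; adjusted p = 0.00876 with an estimated correlation). Ccl5, a chemokine of T cells, fell from 472 ± 120 to 50.7 ± 20.8 CPM (-3.29, SE 0.23), and the CXCR3 ligand Cxcl10 from 1453 ± 421 to 515 ± 152 CPM (-1.49, SE 0.11). Il27, a subunit of interleukin 27, had -1.70 (SE 0.20), and Il15, a growth factor of NK cells and memory T cells, -1.33 (SE 0.17). The 1 gene that rose was the CXCR2 ligand Cxcl3, with 1.12 (SE 0.21), named after its value was seen.

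Targets of NF-kB and pattern receptors changed in part. In the NF-kB and TNF list 5 of 26 fell and 1 rose (10 lower and 1 higher adjusted over the list alone), with a median of -0.21 (camera adjusted p = 2.6e-04; adjusted p = 0.0520 with an estimated correlation), and of -0.11 with the mitochondrial covariate (adjusted p = 0.0561). Cd40, the receptor that the antibody binds, fell from 91.4 ± 30.9 to 18.7 ± 8.19 CPM (-2.32, SE 0.15). The inhibitor genes Nfkbie and Nfkbib both had -0.67, and Ier3, an immediate early gene, rose from 1840 ± 381 to 2806 ± 609 CPM (0.60, SE 0.10). In the pattern recognition and inflammasome list 7 of 27 fell and none rose (9 lower adjusted over the list alone), with a median of -0.39 (camera adjusted p = 6.6e-05; adjusted p = 0.0663 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acid, fell from 1091 ± 184 to 490 ± 81.3 CPM, and Gsdmd, which forms the pore of pyroptosis, from 259 ± 34.0 to 151 ± 22.9 CPM (SD, n = 8). The receptors Clec7a and Tlr2 had log2 fold changes of -0.66 and -0.73. With library totals Nfkbie, Clec7a and Tlr2 were no longer called, at adjusted p of 0.0507, 0.0759 and 0.0824, and without the mouse block Nfkbie and Clec7a had 0.145 and 0.0625.

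In the list of checkpoint ligands and costimulation 3 of 13 genes fell and 1 rose (3 lower and 2 higher adjusted over the list alone). Cd274, which encodes PD-L1, fell from 957 ± 331 to 311 ± 115 CPM (-1.67, SE 0.18), together with Cd40 and with Icosl, the ligand of ICOS, at -0.70 (SE 0.16). Havcr2, which encodes TIM-3, rose from 28.2 ± 7.14 to 58.9 ± 19.6 CPM (1.04, SE 0.22), higher in 7 of 8 mice. Havcr2 was not called with no filter (adjusted p = 0.0554), with the mitochondrial covariate (0.323) or without any 1 of the mice other than mouse 7 (0.0727 to 0.108), at log2 fold changes of 1.01, 1.27 and 0.96 to 1.06. The list as a whole was not called (camera adjusted p = 0.0552), and its median of -0.21 and mean of 0.061 had opposite signs. Icosl was no longer called with library totals (adjusted p = 0.106) or without the mouse block (0.145).

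Most granule genes were not called. Of 18 secondary and tertiary granule genes 4 fell and none rose (8 lower and 1 higher adjusted over the list alone), with a median of -0.40 (camera adjusted p = 6.0e-04; adjusted p = 0.0324 with an estimated correlation). Lysozyme, Lyz2, fell from 11441 ± 2650 to 7558 ± 1522 CPM, Ngp, neutrophilic granule protein, from 3119 ± 1422 to 2075 ± 1106 CPM, and lactoferrin, Ltf, had a log2 fold change of -1.09 (SE 0.21). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, had -0.85 (SE 0.17). None of 6 primary granule genes was called (1 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.398), with 1506 ± 203 and 1150 ± 293 CPM for Gpi1, a glycolytic enzyme gene that is also on the glycolysis list and holds most of the summed level, and 69.7 ± 18.8 and 78.4 ± 30.0 CPM for Ctsc in WT and Ifngr1_KO. Without the mouse block Lyz2, Ngp, Ltf and Cybb were no longer called, at adjusted p of 0.0635, 0.447, 0.278 and 0.0883, and with the mitochondrial covariate they had 0.320, 0.0743, 0.784 and 0.784. Their log2 fold changes with the covariate were -0.50, -0.77, -0.56 and -0.50.

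In the oxidative burst and nitric oxide list 4 of 19 fell and none rose (5 lower adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.00996; adjusted p = 0.151 with an estimated correlation, and 0.0673 with library totals), and of -0.12 with the mitochondrial covariate (adjusted p = 0.0585). Nos2, the inducible nitric oxide synthase, fell from 52.3 ± 31.1 to 9.20 ± 6.00 CPM (-2.55, SE 0.40). Acod1, which makes itaconate, fell from 4331 ± 847 to 2282 ± 534 CPM (-0.94, SE 0.10), and the superoxide dismutase Sod2 from 1323 ± 165 to 944 ± 110 CPM (SD, n = 8). Fc and complement genes had 2 of 16 lower and none higher (5 lower adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.00347; adjusted p = 0.151 with an estimated correlation). These were Fcgr4, an activating IgG receptor, with -1.34 (SE 0.13), and complement factor B, Cfb, with -1.27 (SE 0.22), the latter not called without the mouse block (adjusted p = 0.0682).

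Among neutrophil aging and trafficking receptors 3 of 17 fell and none rose (7 lower and 1 higher adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.00317; adjusted p = 0.409 with an estimated correlation), and of -0.058 with the mitochondrial covariate (adjusted p = 0.758). The adhesion molecule Icam1 went from 3664 ± 859 to 2148 ± 728 CPM, the marrow-homing receptor Cxcr4 from 219 ± 63.0 to 132 ± 40.1 CPM and Ptafr, the receptor of platelet-activating factor, from 554 ± 131 to 399.6 ± 80.8 CPM (SD, n = 8). The mature neutrophil identity list was not called (camera adjusted p = 0.0964, median -0.22), with 2 of 22 members lower and none higher, also when adjusted over the list alone. The 2 were Hdc, which makes histamine, from 2992 ± 352 to 1515 ± 410 CPM, and the formyl peptide receptor Fpr1, with -0.41 (SE 0.09). Without mouse 7 the adjusted p of this list was 0.00417. Without the mouse block Icam1, Cxcr4, Ptafr and Fpr1 were no longer called, at adjusted p of 0.0873, 0.0779, 0.146 and 0.150.

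Apoptosis and survival genes were not called as a list (camera adjusted p = 0.351, median -0.049). Here 2 of 24 fell and none rose (2 lower and 2 higher adjusted over the list alone), among them the BH3-only gene Bid with -0.73 (SE 0.15). Bid was not called with library totals (adjusted p = 0.0758), without mouse 3, 5, 6, 8 or 9 (0.0765 to 0.0952) or with the mitochondrial covariate (-0.32, 0.892). None of 17 glycolysis genes was called, by either adjustment (adjusted over all genes or adjusted over the list alone; camera adjusted p = 0.0886, median -0.20), with Gapdh at 4141 ± 567 CPM in WT and 4239 ± 677 CPM in Ifngr1_KO and Pkm at 4020 ± 400 and 3293 ± 811 CPM. The same held for 18 cell cycle genes (none adjusted over the list alone; camera adjusted p = 0.853, median -0.18), with Hmgb2 at 97.1 ± 14.4 and 112 ± 50.6 CPM and Tubb5 at 29.3 ± 7.11 and 25.6 ± 7.38 CPM. Of 18 stress and immediate early genes 1 rose, Btg2, an antiproliferative gene, from 1134 ± 260 to 2078 ± 484 CPM, and none fell (1 higher adjusted over the list alone). That list had a median of 0.41 (camera adjusted p = 0.123; 0.0193 without mouse 7).

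The mitochondrial and ribosomal lists were called higher with the preset correlation and not with an estimated one. None of the 13 mitochondrial mRNAs was called over all genes, while all 13 were higher adjusted over the list alone, with a median of 1.19 (camera adjusted p = 5.7e-09; adjusted p = 0.209 with an estimated correlation). The level of mt-Co1 was 1600 ± 553 CPM in WT and 2800 ± 1214 CPM in Ifngr1_KO, and that of mt-Cytb 956 ± 532 and 2107 ± 990 CPM (SD, n = 8), each higher in 6 of 8 mice. None of the 33 ribosomal protein genes was called by either adjustment (none adjusted over the list alone), with a median of 0.30 (camera adjusted p = 7.3e-04; adjusted p = 0.544 with an estimated correlation, and 0.0563 without mouse 7). Rps9 had 293 ± 51.5 and 330 ± 133 CPM and Rplp0 187 ± 28.8 and 231 ± 47.6 CPM. Their joint share of counts was higher in Ifngr1_KO in 8 of 8 mice, at 0.131 ± 0.0151% and 0.183 ± 0.0618% (exact sign-flip p = 0.00781, adjusted p = 0.0469), while their summed TMM-scaled CPM was higher in 6 of 8. With the mitochondrial share added to the model, 65 genes were lower and 4 higher, of which 68 were among the 276, and 43 of the genes chosen by rule were no longer called.

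Among markers of other cell types that the gate could hold, 4 genes were called, all lower. In the monocyte list 2 of 12 genes fell and none rose, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.00994; adjusted p = 0.152 with an estimated correlation), and the summed level was lower in 8 of 8 mice. They were Ctss and Ly6c2, the latter from 1212 ± 210 to 741 ± 194 CPM. In the Kupffer cell and macrophage list 1 of 8 fell, the same adjusted over the list alone, Adgre1, which encodes F4/80, from 76.5 ± 25.8 to 36.03 ± 14.5 CPM (camera adjusted p = 0.0964, median -0.24). In the B and plasma cell list 1 of 8 fell, the same adjusted over the list alone, the immunoglobulin heavy chain gene Ighm, from 198 ± 54.5 to 57.6 ± 10.3 CPM (-1.75, SE 0.13; camera adjusted p = 0.298). The median of that list was 0.31, opposite in sign to Ighm.

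No member was called, over all genes or adjusted over the list alone, among 16 hepatocyte, 5 dendritic, 4 T cell, 5 NK cell, 3 eosinophil, basophil and mast cell, 6 endothelial and stellate, and 9 erythroid and platelet genes. Their camera adjusted p were 0.866, 0.866, 0.940, 0.991, 0.866, 0.940 and 0.400 in that order, with medians of 0.029, 0.69, 0.25, -0.077, 0.25, -0.66 and 0.29. The most abundant of these markers were the hepatocyte gene Hpx, at 1581 ± 1126 CPM in WT and 1724 ± 1355 CPM in Ifngr1_KO, and Trf, at 538 ± 248 and 409 ± 238 CPM. Haemoglobin genes had 152 ± 75.2 and 205 ± 133 CPM for Hba-a2 and 114 ± 60.6 and 122 ± 73.7 CPM for Hbb-bs. The endothelial gene Stab1 had 31.1 ± 15.3 and 46.4 ± 15.9 CPM and Pecam1 4.19 ± 0.938 and 4.96 ± 2.15 CPM. Bst2 of the dendritic list had 112 ± 21.3 and 87.9 ± 17.1 CPM and Tcf4 2.14 ± 3.23 and 2.36 ± 1.75 CPM. For Cd3d, Cd247, Nkg7, Il2rb and Ear2 all group means lay at or under 7.89 CPM, and Siglecf had 9.84 ± 5.86 and 10.2 ± 3.70 CPM (SD, n = 8). The sign of the camera test differed from that of the median for the hepatocyte, T cell and B and plasma cell lists, and the mean of the eosinophil, basophil and mast cell list was -0.41.

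Of the 33 lists, 15 were called lower and 2 higher with the preset correlation. With an estimated correlation 6 stayed lower, namely the IFN-gamma, guanylate-binding and immunity-related GTPase, MHC class I, immunoproteasome, cytokine and chemokine, and secondary and tertiary granule lists, and none stayed higher. Of the 229 genes called lower, 45 were on the interferon and MHC lists, and 149 were on no list.

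Genes near Ptprc, the locus used for the sort, were called more often than genes elsewhere. Within 20 Mb of Ptprc (chromosome 1, 138062861 to 138175708) 9 of 122 tested genes were called, 7 lower and 2 higher, or 7.38% against 2.75% in the rest of the genome. Chil1, which encodes the chitinase-like protein YKL-40 (ENSMUSG00000064246, 134182176 to 134190181), fell from 17190 ± 2682 to 4138 ± 915 CPM (-2.07, SE 0.09, adjusted p = 5.6e-07). Ctse (131638306 to 131675505) fell by 4.83 on the log2 scale (SE 0.15), and Cyb5r1, a cytochrome b5 reductase (134405559 to 134411740), from 352 ± 42.9 to 91.7 ± 14.5 CPM (-1.95, SE 0.12). Mybph, a myosin-binding protein gene (134193448 to 134201232), went from 5.55 ± 1.79 to 0.138 ± 0.264 CPM, and Btg2 (134075170 to 134079120) rose by 0.86 (SE 0.10). The other 4 called genes, Cxcr4, Sox13, Csrp1 and Uchl5, had log2 fold changes of -0.73, -6.81, -0.97 and 1.12. Sox13, Csrp1 and Uchl5 were named after their values were seen. Ptprc itself had 725 ± 134 CPM in WT and 698 ± 119 CPM in Ifngr1_KO (adjusted p = 0.811).

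The odds ratio of a call near Ptprc was 2.82 (95% confidence interval 1.24 to 5.63; Fisher's exact test, two-sided, p = 0.00723, adjusted p = 0.0145 over 2 windows). Without mouse 7 it was 1.82 (Fisher's exact p = 0.105). Within 20 Mb of Ifngr1 2 of 74 genes were called, Calhm6 and Vnn3, the latter a vanin-family gene that fell from 110 ± 26.7 to 50.5 ± 17.6 CPM. Vnn3 was not called with library totals (adjusted p = 0.0624), without mouse 2, 3, 4, 6, 8 or 9 (0.0627 to 0.0953) or with the mitochondrial covariate (-0.79, 0.776). That share, 2.70% against 2.79% elsewhere, gave an odds ratio of 0.967 (0.114 to 3.65, Fisher's exact p = 1). Genes are not independent replicates, and neighbouring genes can share regulation, so these p-values describe the spread of calls along the genome.

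**Figure D4:**
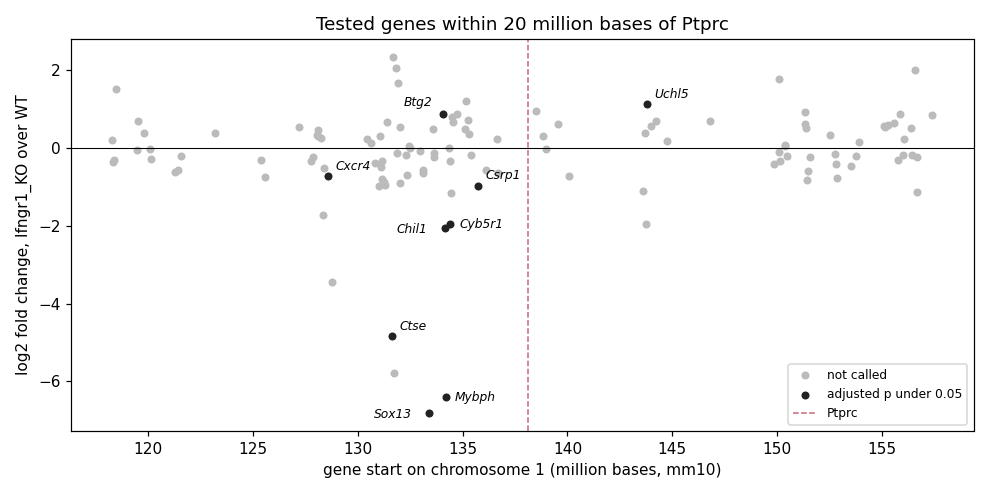
Log2 fold change of Ifngr1_KO over WT against gene start on chromosome 1, in Mb of mm10, for the 122 tested genes within 20 Mb of Ptprc (dashed line); black points were called at an adjusted p under 0.05. Ctse, Sox13, Btg2, Chil1, Mybph and Cyb5r1 start between 131.6 and 134.4 Mb.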

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

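All tests in this part were chosen after the results were seen, except the correlation of genes near Ptprc with interferon-induced genes, whose original bar was written before its value.

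A sample was singled out where its gap to the nearest other sample of its group was large for the range of the group, on the log2 scale for genes. This held in 24 of 220 groups of 8 libraries, where chance gives about 1 in 20, or 11. The Ifngr1_KO library of mouse 7 held 12 of the 24. There, Cenpb and Hmgb2 stood high, at 40.1 and 232 CPM, against at most 11.6 and 117 CPM in the other Ifngr1_KO libraries. Tgtp1 was at 0 CPM, against 3.04 to 23.5 CPM in the others. Tlr2 at 260.8, Hdc at 665, Cd274 at 94.3, Icosl at 53.7, Pkm at 1503 and Vnn3 at 11.5 CPM stood low in this library. Its 10 most abundant genes took 22.8% of counts against 15.2 to 16.02% in the others, ribosomal protein genes took 0.331%, and its median correlation was 0.762.

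The other 12 were spread over 4 mice. In mouse 2, H2-K1 at 6515 CPM and Zbp1 at 719.6 CPM were low in WT, and Psmb8 at 262 CPM and Gsdmd at 106 CPM were low in Ifngr1_KO. In mouse 3, Ctsc at 30.2 CPM and Fpr1 at 1159.8 CPM were low in WT, and P2ry6 at 24.04 CPM and Lyz2 at 4408 CPM were low in Ifngr1_KO. In mouse 5, H2-M3 at 1.76 CPM and Cd247 at 0 CPM were low in Ifngr1_KO, and Stab1 at 1.67 CPM was low in WT. The mitochondrial share of WT mouse 4, 1.19%, was high against 0.294 to 0.660% in the other WT libraries.

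Calls were frequent near Ptprc, with 9 of 122 genes. Lost reads of CD45.1 cells, whose genome may differ from the reference, would lower WT, but 7 of the 9 genes were higher in WT, which argues against lost reads for those 7; for the 2 higher in Ifngr1_KO, Btg2 and Uchl5, no value decides. A segment of another strain linked to Ptprc stayed open, since the odds ratio without the interferon and MHC lists was 3.37 (Fisher's exact p = 0.00242) but none of the 9 genes was on those lists, and CD45 type and genotype cannot be told apart. For dependence on IFN-gamma, the 7 lower genes were correlated with the guanylate-binding and immunity-related GTPase list over the 8 WT libraries. Their median of 0.196 lay under the bar of 0.591 written before (the 5th percentile of sets of IFN-gamma list genes). By that rule the prediction of dependence was not met for the 7 as a set. The correlations went both ways, with Mybph at 0.827, Ctse at -0.382 and Sox13 at -0.635. A rule added after the value was seen left dependence open, since the miss of 0.395 was smaller than the SD of 0.503. That SD is the spread of single genes and not of their median, so it does not undo the miss. In a comparison added after the bar was missed, random sets of 7 were drawn from 177 other lower genes. Of these sets 5.56% had a median at or below 0.196. The 177 genes themselves had a median correlation of 0.486, also under the bar. Their dependence was not tested, so neither the bar nor this comparison decides dependence for the 7.

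Ifngr1_KO libraries kept Ifngr1 reads at 26.1% of WT. WT cells in the CD45.2 gate would bring all their abundant transcripts, but 12 genes with at least 50 CPM in WT had upper limits below the lower limit for Ifngr1, 19.9%, which argues against WT cells as the whole cause. Tgtp1 was at 9.38 CPM, where such a share of WT cells would give 274 CPM. Transcript left by the disrupted allele is a candidate explanation that stays open at 26.1%, because gene totals carry no position along the transcript.

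The median log2 fold change of mitochondrial mRNAs was 1.19, but none of the 13 was called over all genes, their share was higher in 6 of 8 mice (exact sign-flip adjusted p = 0.0625), and the list was not called with an estimated correlation (adjusted p = 0.209). Mouse 7 alone did not carry this median, which was 0.99 without it, and scaling did not, since the lowest median under library totals and DESeq2 size factors was 1.20. Loss of long transcripts as the whole cause was argued against by a median of 1.02 with length trends removed (camera adjusted p = 1.2e-08). In part it may contribute, since the differences in mitochondrial share and length slope had a Pearson r of -0.69 over 8 mice (permutation p = 0.0590, adjusted p = 0.0945 over 3 relations; Spearman rho -0.71, permutation p = 0.0576; r = -0.61 without the 2 farthest mice). An effect of the receptor on mitochondrial transcripts was not separated from RNA quality, marrow donor or sort gate and stays open.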

How the results depend on the processing

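The length offsets and the mitochondrial covariate were chosen after seeing the data; all other alternatives were planned. Against 229 genes lower and 47 higher, DESeq2 gave 572 and 488, limma-voom 425 and 172, the mitochondrial share as a covariate 65 and 4, and an adjusted p under 0.01 gave 124 and 10. The higher count also moved by over 1.5 times with library totals (102, beside 164 lower), no filter (31, beside 196), a mean CPM of at least 10 (126, beside 244) and length offsets (72, beside 299). DESeq2 called all 276 genes, limma-voom 275 and library totals 211. Leaving out 1 mouse gave 144 to 334 lower and 19 to 78 higher: 144 and 19 without mouse 3, 145 and 24 without mouse 6, 144 and 26 without mouse 8, 152 and 22 without mouse 9, and 78 higher without mouse 7. From mouse 2 to mouse 9, leaving out 1 mouse ended the calls of 8, 20, 10, 10, 20, 1, 21 and 18 of the genes chosen by rule. Without the mouse block, which keeps the pairing, 216 were lower and 52 higher, and 215 of the 276 were shared. Of 15 lists lower and 2 higher, camera with an estimated correlation left 6 and 0. Fry called 1 list higher, the mitochondrial one, and the mitochondrial covariate 1, the stress list, which was not among the 2. The lists that lost their call with the estimated correlation, with medians equal to those of the preset one, were type I interferon (-0.24), MHC class II (-0.42), JAK and STAT (-0.43), NF-kB (-0.21), pattern recognition (-0.39), aging (-0.36), oxidative burst (-0.19), Fc and complement (-0.13), monocyte (-0.30), mitochondrial (1.19) and ribosomal (0.30). With the mitochondrial covariate the mitochondrial and ribosomal lists reversed, to -0.10 (adjusted p = 0.280) and -0.016 (0.789), the first by construction. The covariate also ended the calls of the JAK and STAT (-0.10), NF-kB (-0.11), aging (-0.058) and oxidative burst (-0.12) lists, and the mature identity (-0.17) and stress (0.47) lists passed. Mature identity also passed with no filter (-0.25), limma-voom (-0.21), length offsets (-0.29) and fry (-0.22), and glycolysis with no filter (-0.23). Oxidative burst lost its call with library totals (-0.076) and a mean CPM of at least 10 (-0.17). The checkpoint list passed with a mean CPM of at least 10 (-0.15) and fry (-0.21), and the Kupffer list with fry (-0.24), which ended the ribosomal call (0.30). Leaving out 1 mouse gave medians of -0.25 to -0.16 for mature identity, which passed without mouse 7, and of 0.33 to 0.55 for stress, which passed without mouse 7. The range was -0.28 to -0.046 for the checkpoint list, which passed without mouse 6, 8 or 9 (adjusted p = 0.0449, 0.0478 and 0.0337), and 0.17 to 0.40 for the ribosomal list, not called without mouse 7. The odds ratio near Ptprc ran from 1.82, without mouse 7 (Fisher's exact p = 0.105), to 3.76 with 1 mouse left out, was 5.04 with the mitochondrial covariate, and was 5.34 and 2.06 within 10 and 40 Mb, and the pairing correlation was 0.495 over the 1000 genes with the highest mean CPM. Apart from the covariate's own list, the cause was not tested. On simulated counts 22% of genes changed 2-fold were called, so many smaller changes were not detectable at this depth and spread.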

Other observations

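Tests in this part were chosen after the results were seen, except the splits of the samples, which were planned.

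Cd81, a tetraspanin named after its values were seen, rose from 63.0 ± 14.2 to 135.0 ± 26.3 CPM (SD, n = 8; log2 fold change 1.11, SE 0.12, edgeR adjusted p = 3.4e-04), higher in Ifngr1_KO in 8 of 8 mice. Called genes gathered in several places. Among 332 segments of 5 Mb with at least 10 tested genes, the highest counts were 17 of 74 genes on chromosome 17 from 35 to 40 Mb, 10 of 26 on chromosome 11 from 45 to 50, 8 of 84 on chromosome 17 from 30 to 35 and 6 of 40 on chromosome 1 from 130 to 135. Tgtp1 and Tgtp2 lie in the segment of chromosome 11, and the segment of chromosome 1 lies within the window around Ptprc.

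The libraries of a mouse were swapped at random in 100 splits that included the real one. Only the real split called 276 genes, and the highest of the others called 0. Without the block 268 genes were called, and 1 of 100 splits, again the real one, called as many. The highest of the others called 1. In both checks the other splits kept the genotype differences in the counts as spread within groups, which lowers their calls. These counts therefore cannot exclude chance for single genes among the 276.

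Both genotypes of a mouse share its liver and its cytokines, so the levels of interferon-induced genes could follow each other across mice. For the type I list the mean log2 CPM in WT and in Ifngr1_KO had a Pearson r of 0.44 over 8 mice (permutation p = 0.280, adjusted p = 0.280; Spearman rho 0.43, permutation p = 0.299; r = 0.23 without the 2 farthest). For the guanylate-binding and immunity-related GTPase list r was 0.63 (permutation p = 0.0630, adjusted p = 0.0945; rho 0.86, permutation p = 0.0107; r = 0.57 without the 2 farthest). The adjustment covers 3 relations. Neither Pearson test passed, and with 8 mice a shared level stays open for both lists.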
